A study of Homo sapiens with 9 samples.

How the data were processed

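Total RNA of 9 U2OS samples was extracted with TRIzol, depleted of ribosomal RNA with probes, fragmented and copied from random hexamers into Illumina libraries, per the labels' protocols. Groups (KO, delN90, FL) and replicate numbers 1 to 3 were taken from the sample titles. The deposited table held 1 column per library, and all 9 columns matched a sample by the name in its description. For the libraries titled FL that name is Ctrl, so the sample record, not the column name, set the group. No other sample column was present (0 unused).

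The deposited values were FPKM, that is reads per kilobase of gene length and scaled to the reads assigned to genes in the library, as computed by the authors. Per the submitters' processing notes, fastp 0.23.2, STAR 2.7.6a and featureCounts of Subread 1.5.1 were used with genome build GRCh38. The annotation release and the strand setting were not given in the sources used here. Coordinates and gene symbols are those of the deposited table. Without a known strand setting, reads of overlapping and antisense genes cannot be separated. Some overlapping entries carried identical reads in all libraries (10 entries, among them 7SK and RN7SK), so reads were counted for each of them.

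FPKM times gene length came out as a whole multiple of 1 step per library for 100% of values within a tolerance of 0.001, so whole reads and the total of assigned reads per library were recovered. Totals were 19227179, 19655459 and 20301110 in KO, 24702052, 23167600 and 23550793 in delN90, and 22271193, 19350616 and 21510897 in FL. Limma-voom on these reads called 9152, 90 and 9578 genes in the 3 comparisons. The listed genes held 99.644% to 99.681% of these reads, and all 18519 listed genes had at least 10 reads in at least 3 libraries, so genes below that were not analysed here. At these depths 1 read on a gene of median length was worth 0.00924 to 0.0119 FPKM. Replicates were compared by chi-square tests of their reads. The 9 pairs within groups gave 1.36 to 4.08 per gene, above counting error in each pair. This shows only that no 2 files are repeat runs of 1 library, and separate preparations of 1 RNA would also exceed it. The 9 libraries were treated as separate samples because the titles number them as replicates.

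The test written before the data were examined assumed counts. Because the unit was FPKM, limma-trend was used instead, on log2(FPKM + 1) over all listed genes. It fitted all 9 libraries with 1 mean per group and no replicate block (6 residual degrees of freedom), with a robust variance trend. The 3 contrasts were FL minus KO, delN90 minus KO and delN90 minus FL. Benjamini-Hochberg adjusted p under 0.05 counted as a call. A fold change printed as "x-fold" is the ratio of mean FPKM, while log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. R 4.3.3 with limma 3.58.1 was used, and figures were drawn with matplotlib 3.10.9.

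Before the data were examined, 25 gene lists were fixed, among them clock E-box targets, ROR and REV-ERB responsive genes, stress, cell cycle, glucocorticoid and immune lists, and markers of other cell types. Lists were tested with camera, two-sided, at a preset correlation of 0.01, with adjustment over the 25 lists within a comparison, and again with an estimated correlation and with fry. Genes were named by a rule fixed at the same time. It took BMAL1 and CLOCK, the measured E-box targets, the 10 called genes with the largest positive and the 10 with the largest negative log2 fold change (a mean of at least 1 CPM in 1 group, no overlap between libraries of the groups, a symbol other than a clone or locus identifier), and up to 4 members of each other list with the smallest adjusted p. Enrichment of the gene ontology terms given in the deposited table was tested with a one-sided hypergeometric test against the 13581 genes with a term. Comparisons that share libraries were set beside 100 simulations of unchanged groups.

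The fit was tested on 9 simulated libraries over 18519 genes, with changes placed in delN90. Means came from KO, dispersions were averaged over the 3 groups, and depths were those of the real libraries. It called 22% of genes changed 1.2-fold, 84% of those changed 1.5-fold, 98% at 2-fold and 100% at 4-fold, with 6 of 18319 unchanged genes called. The changed genes were drawn from the 6774 well-expressed genes alone, so the share called among lower genes was not measured. A list shifted 1.25-fold had a camera adjusted p of 1.78e-22, and 0 of 24 other lists passed. Genes were simulated independently, so this did not test whether the preset correlation of 0.01 suits the real lists. Estimated correlations reached 0.826, for mitochondrial-encoded mRNAs.

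Alternatives fixed before the data were examined were median-ratio scaling, a minimum mean of 1 CPM, limma-voom on the recovered reads, a replicate block, leaving out each library, protein-coding genes alone with rescaling (GENCODE v29 biotypes, matched for 95.9% of genes), fitting only the 2 groups compared, a log2 fold change of at least 1 in size on the log2(FPKM + 1) scale besides, and the list tests above. Added after seeing the data were pseudocounts of 0.1 and 0.01, a variance prior without the robust step, removal of a GC and length trend (GC known for 95.8% of genes), thinning of all libraries to the smallest total, and subtraction of the median of 50 neighbouring genes.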

Results

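RNA of U2OS cells, an established human osteosarcoma line that is widely used to record circadian rhythms in culture, was sequenced in 3 groups of 3 libraries each. By the design statement of the series, the groups were a BMAL1 knockout (KO), the knockout with full-length BMAL1 added back (FL, a label that the BMAL1 transcript goes against, as described below), and the knockout with a BMAL1 form whose label, delN90, names a deletion of 90 residues at the N-terminus. All 9 libraries came from cells collected 2 h after synchronization with DXMS. BMAL1 is the transcription factor that pairs with CLOCK, binds E-box elements and drives the positive arm of the circadian clock. The series title places the study in work on phase separation of BMAL1 and transcriptional hubs, so the comparisons ask which transcripts differ when BMAL1 is absent, full-length or truncated. Reads assigned to genes numbered 19227179 to 24702052 per library. The table listed 18519 genes in FPKM. Within groups, the median coefficient of variation over 6774 well-expressed genes was 3.02% in KO, 4.12% in delN90 and 3.38% in FL. Nothing in the labels said that the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

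The targeted gene was examined first. BMAL1 (GRCh38 chromosome 11, 13276652 to 13387263, plus strand) stood at 3.13 ± 0.305 FPKM in KO (SD, n = 3), 132.3 ± 7.78 FPKM in delN90 and 2.57 ± 0.126 FPKM in the libraries labelled FL. Reads on the gene numbered 394, 402 and 490 in KO, 24160, 20282 and 21145 in delN90, and 397, 327 and 401 in FL. The 95% exact Poisson interval of the lowest value, 327 reads, ran from 292.5 to 364.4, which covers counting error only. Thus BMAL1 transcript was 42.3-fold above KO in delN90 (log2 fold change 5.01, SE 0.060, limma adjusted p = 3.36e-10). In the libraries labelled FL it was not above KO but 1.22-fold below it (log2 fold change −0.21, SE 0.060, limma adjusted p = 0.0177). That small decrease did not pass without KO replicate 3 (adjusted p = 0.0539) or without FL replicate 2 (adjusted p = 0.0600). A full-length transgene counted at this gene would be looked for as a rise, so the transcript went against the FL label, and the libraries are called "labelled FL" below. Their GEO descriptions and the column names of the deposited table call them Ctrl. Transcript in KO does not test the knockout, since a frameshift can leave the transcript in place. CLOCK, the partner of BMAL1, stood at 7.17 ± 0.227 FPKM in KO, 7.44 ± 0.516 in delN90 and 6.53 ± 0.0703 in the libraries labelled FL. CLOCK passed the test between delN90 and FL (log2 fold change 0.16, adjusted p = 0.0175), and that call was lost without any 1 of 3 libraries, delN90 replicate 1 (adjusted p = 0.0563), delN90 replicate 3 (0.0621) or FL replicate 2 (0.0503). Between FL and KO, CLOCK (log2 fold change −0.12, adjusted p = 0.0641) passed with a replicate block (0.0431), without delN90 replicate 2 (0.021), with the 2 groups fitted alone (0.0288) and after subtraction of the median of 50 neighbouring genes (−0.32, 0.000608).

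Of 19 clock E-box targets, 10 were higher and 2 lower in the libraries labelled FL than in KO, with the BMAL1 transcript itself against that label (camera adjusted p = 0.00133, adjusted p = 0.151 with an estimated correlation). NR1D2, a nuclear receptor of the REV-ERB pair that represses BMAL1, rose 5.59-fold, from 2.00 ± 0.143 to 11.2 ± 0.719 FPKM (SD, n = 3 per group). BHLHE41, an E-box-binding repressor also called DEC2, rose 4.24-fold, from 1.69 ± 0.128 to 7.16 ± 0.568 FPKM. The period gene PER3 rose 2.03-fold, from 5.41 ± 0.136 to 10.97 ± 0.752 FPKM. The PAR-bZIP factors TEF and DBP rose 2.22-fold and 2.46-fold, and the second REV-ERB gene NR1D1 rose 2.47-fold, from 1.00 ± 0.0794 to 2.47 ± 0.282 FPKM. NR1D1 overlaps THRA on the opposite strand, and the strand setting of the counting was not given, so its reads are uncertain.

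Of the 19 measured genes of the clock E-box target list, 10 rose, 2 fell and 7 did not pass in the libraries labelled FL against KO, and the counts were the same when adjusted over the list alone. KLF10 rose 1.62-fold, BHLHE40 1.52-fold, NAMPT 1.30-fold and SMARCD3 1.28-fold. CRY2 fell, from 1.86 ± 0.112 to 1.52 ± 0.0459 FPKM, and GPR176, an orphan receptor of the circadian pacemaker, fell from 7.63 ± 0.487 to 5.56 ± 0.168 FPKM. PER1 (log2 fold change 0.14, adjusted p = 0.0877), PER2 (0.13, adjusted p = 0.166), CRY1 (−0.07, adjusted p = 0.212), WEE1 (−0.07, adjusted p = 0.221), RORA, USP2 and TSPAN4 did not pass. Median-ratio scaling of the libraries brought PER1 past the threshold (adjusted p = 0.0388), and limma-voom brought PER1 (0.00353) and PER2 (0.0219) past it. PER1 also passed without KO replicate 2 (0.0451), with protein-coding genes alone (0.0428) and after removal of the GC and length trend (0.04). Subtraction of the median of 50 neighbouring genes brought both PER1 (0.0244) and PER2 (0.0105) past it. The list's median log2 fold change was 0.29 (camera adjusted p = 0.00133). This call was lost when the correlation between genes was estimated from the data, with adjusted p = 0.151 with an estimated correlation. The genes of the opposite arm, driven through ROR and REV-ERB, had 3 of 8 members lower and none higher (camera adjusted p = 0.153). NPAS2, a paralog of CLOCK, fell from 1.96 ± 0.0966 to 0.755 ± 0.0610 FPKM, NFIL3 1.63-fold and E2F8 1.26-fold. The E2F8 call was lost without KO replicate 1 (adjusted p = 0.0611) or without FL replicate 1 (0.0534).

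**Figure D1:**
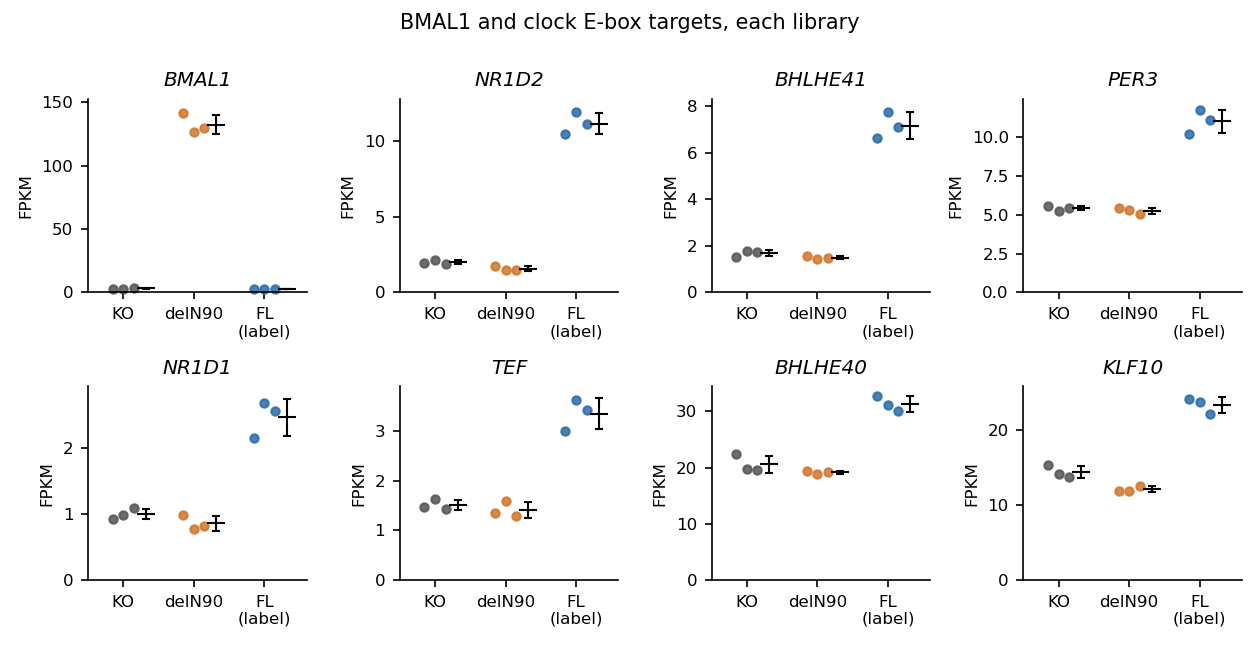
FPKM of BMAL1 and 7 clock E-box targets, with 1 point per library (3 per group) and black bars for the mean and SD. BMAL1 was at 132.3 FPKM in delN90 and at 3.13 and 2.57 FPKM in KO and the libraries labelled FL, while NR1D2 was at 11.2 FPKM in the libraries labelled FL and at 2.00 and 1.58 FPKM in KO and delN90.

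The difference between the libraries labelled FL and KO reached far beyond clock genes. Among genes named by rank, cardiac troponin T (TNNT2) rose 31-fold, from 0.850 ± 0.0818 to 26.4 ± 2.1 FPKM, and slow skeletal and cardiac troponin C (TNNC1) rose 15.8-fold, from 6.40 ± 0.185 to 101.3 ± 1.79 FPKM. Type III collagen (COL3A1) rose 32.2-fold, the chemokine CXCL14 12.4-fold, argininosuccinate synthase (ASS1) 10.6-fold and the retinoic acid-binding protein CRABP2 8.48-fold. The cancer-testis genes MAGEC1 and GAGE2A were near 0 in KO (0.0238 ± 0.0206 and 0.0294 ± 0.0510 FPKM) and at 7.85 ± 0.373 and 12.3 ± 0.889 FPKM in the libraries labelled FL. RFPL4A (10.6-fold higher) and the pseudogene NCOR1P3 (0.169 ± 0.168 FPKM in KO and 23.1 ± 1.14 in FL) belong with GAGE2A to families of near-identical copies, so their reads are uncertain. On the lower side, the receptor tyrosine kinase ROS1 fell 8.69-fold, the steroid dehydrogenase HSD17B3 5.97-fold, the annexin ANXA10 3.74-fold and the lysosomal fucosidase FUCA1 3.72-fold. The hair keratin KRT81 fell 2.89-fold, from 321.1 ± 3.52 to 111.1 ± 10.2 FPKM, and its neighbouring pseudogene KRT87P fell 3.30-fold, with reads that may be shared between the copies. LINC01173, a non-coding RNA, fell 14.2-fold. The small RNAs RNU2-2P and RNA5-8SN3 and the pseudogene HSP90AA2P also fell, but each has near-identical copies elsewhere in the genome, and 5.8S ribosomal RNA is a target of depletion.

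In all, limma called 8754 of 18519 genes between the libraries labelled FL and KO, 3957 higher and 4797 lower, with a median absolute log2 fold change of 0.26. Of these, 253 had a log2 fold change of at least 1 in size on the log2(FPKM + 1) scale, 156 higher and 97 lower, a limit that leaves out low genes whose mean FPKM changed more than 2-fold, such as TEF and DBP. The first principal component held 74.1% of the variance and set the libraries labelled FL (28.1 to 28.7) apart from the other 6 (−15.6 to −13.3). Which direction held more genes depended on scaling, with 4499 higher and 4246 lower by median-ratio scaling and 4735 higher and 4417 lower by limma-voom.

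Several gene lists moved as groups between the libraries labelled FL and KO. Immediate early genes, the first transcription factors switched on by growth signals, had 14 of 22 members higher and 2 lower. EGR2 rose 8.28-fold, NR4A3 5.94-fold, NR4A1 2.27-fold and SRF 1.66-fold (list median log2 fold change 0.55, camera adjusted p = 5.39e-05, adjusted p = 0.297 with an estimated correlation). NF-kB and cytokine genes had 11 of 16 higher and 1 lower, among them CXCL8 (15.7-fold, from 0.218 ± 0.144 to 3.43 ± 0.521 FPKM), CCL2 (15.2-fold) and TNFAIP3 (2.20-fold), with a list median of 0.46 (camera adjusted p = 5.16e-05, adjusted p = 0.164 with an estimated correlation). Glucocorticoid-induced genes had 12 of 22 higher and 2 lower, led by FKBP5, which rose 2.64-fold from 6.61 ± 0.312 to 17.5 ± 0.788 FPKM (list median 0.17, camera adjusted p = 0.00189, adjusted p = 0.122 with an estimated correlation). The integrated stress and unfolded protein response list had 14 of 24 higher and 6 lower. The endoplasmic reticulum (ER) chaperones SDF2L1 (2.39-fold), HYOU1 (2.31-fold) and HSPA5 (1.84-fold) rose, and the stress sensor SESN2 fell, from 2.72 ± 0.190 to 1.29 ± 0.0369 FPKM (list median 0.28, camera adjusted p = 0.00189, adjusted p = 0.164 with an estimated correlation). Cytosolic ribosomal protein genes had 18 of 25 higher and none lower, including RPL7A (1.68-fold) and RPS3 (1.45-fold), with a list median of 0.23 (camera adjusted p = 1.15e-07, adjusted p = 0.297 with an estimated correlation).

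Lists that moved down in the libraries labelled FL were led by cell division and chromatin genes. G2/M genes had 21 of 24 members lower and 1 higher. BUB1B fell 1.64-fold from 67.7 ± 1.98 to 41.4 ± 1.74 FPKM, and AURKA, a mitotic kinase, fell 1.58-fold (list median −0.30, camera adjusted p = 5.19e-08, adjusted p = 0.164 with an estimated correlation). Replication-dependent histone genes had 7 of 10 lower, including H1-2 (2.24-fold lower, from 477 ± 18.4 to 213.2 ± 2.82 FPKM) and H2AC6 (2.34-fold), with a list median of −0.72 (camera adjusted p = 4.2e-04, adjusted p = 0.122 with an estimated correlation). p53 targets had 14 of 22 lower and 1 higher, with MDM2 1.73-fold, FDXR 1.74-fold and XPC 1.56-fold lower (list median −0.20, camera adjusted p = 3e-04, adjusted p = 0.122 with an estimated correlation). The coactivator and Mediator list had 13 of 22 lower and 2 higher, such as TRIM28 (1.42-fold lower) and NCOR1 (1.27-fold lower), with a median of −0.15 (camera adjusted p = 0.00672, adjusted p = 0.297 with an estimated correlation). Interferon-stimulated genes had 5 of 15 lower and none higher, with ISG15 3.45-fold and IFI44 2.79-fold lower (list median −0.09, camera adjusted p = 0.0344, adjusted p = 0.297 with an estimated correlation). S phase genes split, with 6 of 24 higher, among them CDC45 (1.30-fold), and 5 lower, among them RRM2 (1.49-fold) and PCNA (1.32-fold), with camera adjusted p = 0.519.

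Markers of other cell types were tested as 3 lists. Of 5 measured epithelial markers, 3 were higher in the libraries labelled FL (camera adjusted p = 0.0344, adjusted p = 0.164 with an estimated correlation), the most abundant of these being EPCAM, at 4.25 ± 0.268 against 2.34 ± 0.0789 FPKM. Haematopoietic markers had 1 of 3 higher (LCP1, 1.34 ± 0.0381 against 0.573 ± 0.0388 FPKM), and embryonic kidney line markers had 3 of 8 higher and 3 lower, including NEFL, which fell 2.66-fold. Neither of these 2 lists passed (camera adjusted p = 0.728 and 0.884). The remaining lists did not pass camera either, with members higher and lower numbering 4 and 4 of 16 for clock modifiers, 7 and 5 of 15 for heat shock, 6 and 10 of 23 for cholesterol biosynthesis, and 7 and 10 of 23 for hypoxia and glycolysis. The counts were 9 and 5 of 17 for NRF2 targets, 8 and 8 of 23 for extracellular matrix and TGF-beta genes, 4 and 1 of 10 for osteoblast genes, 2 and 0 of 13 for mitochondrial-encoded mRNAs, and 5 and 6 of 25 for nuclear OXPHOS genes. Single members still moved far, such as the small heat shock protein CRYAB (4.04-fold higher), NDRG1 (1.83-fold higher), COL5A2 (2.94-fold higher), TIMP3 (3.47-fold higher), COL4A2 (1.53-fold lower) and the osteoblast phosphatase ALPL (3.01-fold higher). Adjusted over the list alone, the counts higher and lower were 14 and 2 for glucocorticoid-induced genes, 15 and 2 for immediate early genes, 2 and 14 for the coactivator list and 1 and 15 for p53 targets. They were unaltered for the other lists that passed camera. Median, mean and test differed in sign for cholesterol biosynthesis, extracellular matrix, haematopoietic and embryonic kidney lists.

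By camera, 12 of the 25 lists passed between the libraries labelled FL and KO, and none did with an estimated correlation (smallest adjusted p = 0.122). By fry, which asks whether a list's genes move one way on balance without comparing them with other genes, 20 passed.

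ER chaperone genes were higher in delN90 than in KO. HSPA5, the main ER chaperone BiP, rose 1.47-fold, from 113.1 ± 0.817 to 166.3 ± 1.83 FPKM (SD, n = 3 per group, log2 fold change 0.55, SE 0.021, limma adjusted p = 5.9e-06). Calreticulin (CALR) rose 1.31-fold, from 726.1 ± 4.03 to 951.1 ± 20.1 FPKM, SDF2L1 rose 1.68-fold, HYOU1 1.35-fold, and HSP90B1 1.22-fold. DNAJB11 rose from 36.6 ± 0.618 to 45.7 ± 0.245 FPKM. The disulfide isomerases PDIA3 and PDIA6 rose 1.24-fold and 1.17-fold, and PDIA4 rose from 61.1 ± 0.751 to 73.4 ± 1.04 FPKM. DNAJC3, CANX, MANF, CRELD2 and HERPUD1 rose 1.37-fold, 1.17-fold, 1.30-fold, 1.34-fold and 1.32-fold. The stress transcription factors DDIT3, also called CHOP, and XBP1 rose 1.56-fold (7.10 ± 0.664 to 11.1 ± 0.568 FPKM) and 1.42-fold (26.3 ± 0.979 to 37.2 ± 3.63 FPKM).

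Altogether limma called 20 of 18519 genes between delN90 and KO, 19 higher and 1 lower, and 1423 genes had an unadjusted p under 0.05. Besides BMAL1 itself and the 16 genes above, the higher genes were NACA2, a retrocopy whose reads may come from NACA, and ENSG00000250746, given by identifier alone. The only lower gene was CCDC163, at 2.32 ± 0.300 FPKM in KO and 0.908 ± 0.281 in delN90 (adjusted p = 0.0486). BMAL1 alone had a log2 fold change of at least 1 in size, since CCDC163, at 2.56-fold lower by mean FPKM, stood at −0.81 on the log2(FPKM + 1) scale. The genes here that fall outside the rule for named genes were named after their values were seen. Of the 24 measured genes of the integrated stress and unfolded protein response list, 9 rose and none fell, or 10 rose when adjusted over the list alone (median log2 fold change 0.11, camera adjusted p = 2.91e-15, adjusted p = 0.0142 with an estimated correlation). The 9 were HSPA5, CALR, HYOU1, SDF2L1, PDIA4, HERPUD1, CRELD2, XBP1 and DDIT3, while amino acid response members of the same list such as ATF4 (202.8 ± 4.85 and 196.5 ± 5.26 FPKM in KO and delN90) and ASNS (9.78 ± 0.508 and 10.8 ± 0.496) did not pass. An enrichment test against 13581 annotated genes placed 10 of 18 annotated higher genes in the term endoplasmic reticulum (0.534 expected, hypergeometric adjusted p = 5.19e-08) and 6 in protein folding (0.146 expected, adjusted p = 6.53e-06).

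**Figure D2:**
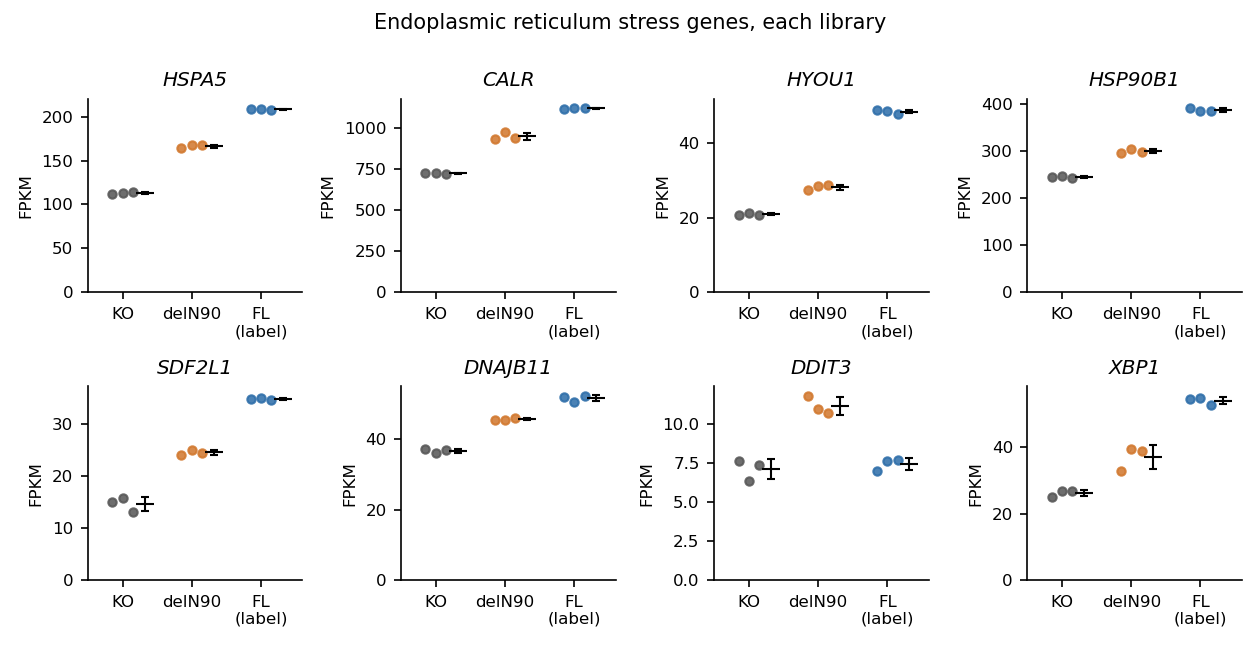
FPKM of 8 ER stress genes that passed the test between delN90 and KO, with 1 point per library and black bars for the mean and SD of 3. HSPA5 was at 113.1 FPKM in KO, 166.3 in delN90 and 208.2 in the libraries labelled FL, whereas DDIT3 was at 7.10, 11.1 and 7.42 FPKM.

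Clock genes did not follow the BMAL1 transcript in delN90. None of the 19 measured E-box targets passed against KO by limma, 3 had an unadjusted p under 0.05, all with lower values, and limma-voom called 1, KLF10 (14.4 ± 0.816 and 12.1 ± 0.418 FPKM in KO and delN90). Adjusted over the list alone, 1 was lower. NR1D2 stood at 2.00 ± 0.143 FPKM in KO and 1.58 ± 0.165 in delN90 (log2 fold change −0.22, adjusted p = 0.427), PER3 at 5.41 ± 0.136 and 5.25 ± 0.194 (−0.04, adjusted p = 0.918), and BHLHE41 at 1.69 ± 0.128 and 1.499 ± 0.0717 (−0.10, adjusted p = 0.723). The list's median log2 fold change was −0.04, with 13 of 19 genes below 0 (camera adjusted p = 0.0337, adjusted p = 0.33 with an estimated correlation, fry adjusted p = 0.161). The camera call was also lost without KO replicate 1 (median −0.03, adjusted p = 0.074), KO replicate 2 (−0.03, 0.0613), delN90 replicate 1 (−0.02, 0.134) or delN90 replicate 3 (−0.01, 0.103).

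Other lists showed small shifts between delN90 and KO without a called gene. Besides the stress list, 3 lists passed camera with both the preset and an estimated correlation, namely p53 targets (median log2 fold change 0.07, estimated-correlation adjusted p = 0.0337), cholesterol biosynthesis (0.06, 0.0342) and extracellular matrix and TGF-beta genes (−0.08, 0.0337). At an unadjusted p under 0.05, 7 of 22 p53 targets and 4 of 23 cholesterol genes had higher values and 10 of 23 matrix genes had lower values. Limma-voom called 0, 0 and 2 of them. Adjusted over the list alone, 3 p53 targets were higher and 5 matrix genes lower. MDM2 stood at 16.6 ± 0.299 FPKM in KO and 18.3 ± 0.346 in delN90 (adjusted p = 0.301), and MMP2 at 20.1 ± 0.578 and 17.5 ± 0.811 (adjusted p = 0.252). The other lists that passed camera lost the call with an estimated correlation. Their medians and estimated-correlation adjusted p were −0.06 and 0.547 for immediate early genes, 0.03 and 0.547 for G2/M genes, 0.04 and 0.454 for heat shock genes, −0.10 and 0.547 for mitochondrial-encoded mRNAs, −0.05 and 0.231 for epithelial markers, and 0.03 and 0.454 for embryonic kidney line markers. Median, mean and test differed in sign for the ROR and REV-ERB list and for histones. In all, 11 of 25 lists passed camera with the preset correlation, 4 with an estimated one, and 5 by fry. The count of 20 genes became 12 without KO replicate 1, 13 without KO replicate 2 and 32 (21 higher, 11 lower) without delN90 replicate 1, a library that stood apart on the third component (−12.9) and held 217.3 FPKM of the small nuclear RNA RN7SK against 71.19 and 103.3 in the other delN90 libraries. It was 10 with the 2 groups fitted alone, 33 with protein-coding genes alone, 31 after subtraction of the median of 50 neighbouring genes, and 90 by limma-voom (59 higher, 31 lower), which kept all 20. The 9 called stress genes became 5 without delN90 replicate 2 or with the 2 groups fitted alone. XBP1 and CRELD2 failed the threshold in most of the fits that left out 1 library, with log2 fold changes in those fits of 0.438 to 0.499 for XBP1 and 0.344 to 0.409 for CRELD2. XBP1 also failed by median-ratio scaling (limma adjusted p = 0.0653) and after removal of the GC and length trend (0.0523). CCDC163 failed whichever library was left out (limma adjusted p = 0.0521 to 0.261). It also failed with a replicate block (0.218), pseudocounts of 0.1 (0.0894) and 0.01 (0.104), and the 2 groups fitted alone (0.194). DDIT3 failed without delN90 replicate 2 (log2 fold change 0.593, adjusted p = 0.0539) and with the 2 groups fitted alone (0.581, 0.0785).

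Direct comparison of the truncated form with the libraries labelled FL gave nearly the mirror image of the comparison of those libraries with KO. A difference between cell populations unrelated to BMAL1 would also give a mirror image, since delN90 cells are knockout cells by the design statement. NR1D2 was 7.07-fold lower in delN90 (1.58 ± 0.165 against 11.2 ± 0.719 FPKM), BHLHE41 4.78-fold lower, NR1D1 2.87-fold, TEF 2.38-fold, PER3 2.09-fold and KLF10 1.93-fold lower. PER1 also passed here (4.89 ± 0.354 against 5.90 ± 0.313 FPKM, adjusted p = 0.0118). TNNT2 was 37.6-fold, COL3A1 50.1-fold, CXCL14 17.3-fold and TNNC1 15.3-fold lower in delN90, and LINC01173 (14.5-fold), ROS1 (9.27-fold), the adhesion protein NECTIN4 (6.80-fold) and ANXA10 (3.60-fold) were higher. BMAL1 was 51.6-fold higher in delN90 (log2 fold change 5.22, SE 0.060, adjusted p = 1.16e-10), which again goes against the FL label.

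Between delN90 and the libraries labelled FL, limma called 8886 genes, 4806 higher and 4080 lower, 264 of them with a log2 fold change of at least 1 in size on the log2(FPKM + 1) scale. Of the 19 E-box targets, 11 were lower and 2 higher (CRY2 and GPR176), with the same counts adjusted over the list alone and a median log2 fold change of −0.29 (camera adjusted p = 0.00117, adjusted p = 0.126 with an estimated correlation). HYOU1 (1.72-fold), CRELD2 (1.51-fold) and HSPA5 (166.3 ± 1.83 against 208.2 ± 0.558 FPKM) were lower in delN90 than in the libraries labelled FL, whereas PDIA3 was higher (60.4 ± 1.27 against 54.5 ± 1.38 FPKM, adjusted p = 0.00259) and PDIA6 did not pass (adjusted p = 0.222). DDIT3 was higher in delN90 (log2 fold change 0.52, adjusted p = 1.62e-04), as was SESN2 (2.36-fold), and the stress list as a whole had 14 of 24 lower and 7 higher (camera adjusted p = 0.0468, adjusted p = 0.277 with an estimated correlation). G2/M genes had 21 of 24 higher, p53 targets 16 of 22 higher, histones 7 of 10 higher, ribosomal proteins 18 of 25 lower and immediate early genes 15 of 22 lower and 2 higher. MDM2 was 1.91-fold higher in delN90, H1-2 2.32-fold higher, RPL7A 1.69-fold lower and EGR2 11.6-fold lower. Mitochondrial-encoded mRNAs had 7 of 13 lower and none higher (camera adjusted p = 0.0353, adjusted p = 0.648 with an estimated correlation). By camera, 13 of 25 lists passed in this comparison, none with an estimated correlation (smallest adjusted p = 0.0931), and 20 passed by fry. Median, mean and test differed in sign for clock modifiers, heat shock, nuclear OXPHOS, haematopoietic and embryonic kidney lists.

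At the genes that separated the libraries labelled FL from KO, delN90 lay near the KO level. Of the 8754 genes, delN90 differed from FL towards KO at 7618 (87%), away from KO at 2, and did not pass at 1134. Among the 253 genes with a log2 fold change of at least 1 in size, 251 (99.2%) differed towards KO. For these 253 genes, the median share of the difference between FL and KO that delN90 reached was 0.00585 (quartiles −0.0346 and 0.057). By the design statement, delN90 cells are knockout cells. At a gene that differs between the cell populations for another reason, delN90 would also lie at the KO level. For example, 50 genes on chromosome 1 from 14404 to 1662602 had a median of −0.771 in FL against KO and 0.775 in delN90 against FL. The counts above thus do not show what the truncated protein lacks. Both comparisons use the FL libraries, so fold changes correlate without any effect. Across genes, which are not independent replicates, r was −0.955 against −0.499 in 100 simulations of unchanged groups, and the covariance was −0.0951 against −0.00243. The simulations gave 0.01 shared calls on average, a count near 0 by construction because no group was changed in them. Independent lists of these sizes would share 872 genes higher in FL and 1240 lower in FL.

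**Figure D3:**
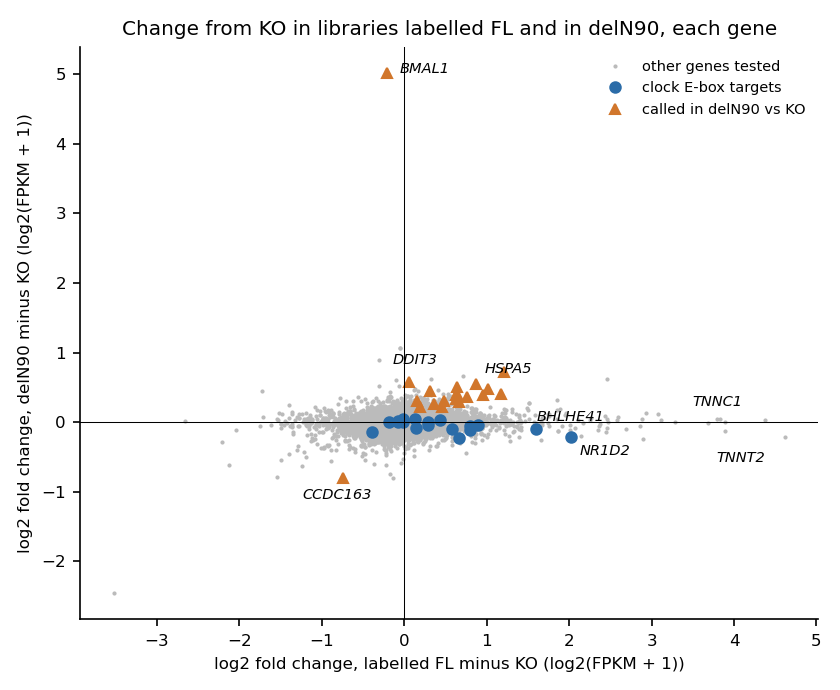
Log2 fold change on the log2(FPKM + 1) scale of every gene tested, with the libraries labelled FL minus KO on the horizontal axis and delN90 minus KO on the vertical axis (blue circles, 19 clock E-box targets, and orange triangles, 20 genes called between delN90 and KO). E-box targets spread along the horizontal axis, with NR1D2 at 2.02 and −0.22, while BMAL1 lies at −0.21 and 5.01.

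The genes that rose in delN90 over KO overlapped those that rose in the libraries labelled FL over KO. Of the 19 higher genes, 17 were also higher in FL, where independent lists would share 4.06, and CCDC163 was lower in both (0.259 expected). The CCDC163 call between delN90 and KO was lost whichever library was left out. HSPA5 reached 208.2 ± 0.558 FPKM in the libraries labelled FL, HYOU1 48.5 ± 0.468 and CALR 1120 ± 4.09. BMAL1 was the gene of opposite direction, and DDIT3 did not pass between FL and KO (7.42 ± 0.386 FPKM in FL, adjusted p = 0.492). Simulated unchanged groups against the shared KO libraries gave 0.02 shared calls on average, against 18 observed. With no group changed, few genes can be called in either comparison, so the simulated count is near 0 by construction. It does not show how much of the overlap comes from the shared KO libraries. Across genes, r between these 2 comparisons was 0.123 against 0.501 simulated, and the covariance was 0.00368 against 0.00244. The 3 KO libraries are too few to divide between the 2 comparisons, so part of the overlap may come from the shared KO libraries. The 18 shared genes became 10 without KO replicate 1 and 10 without KO replicate 2, and limma-voom gave 59.

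**Figure D4:**
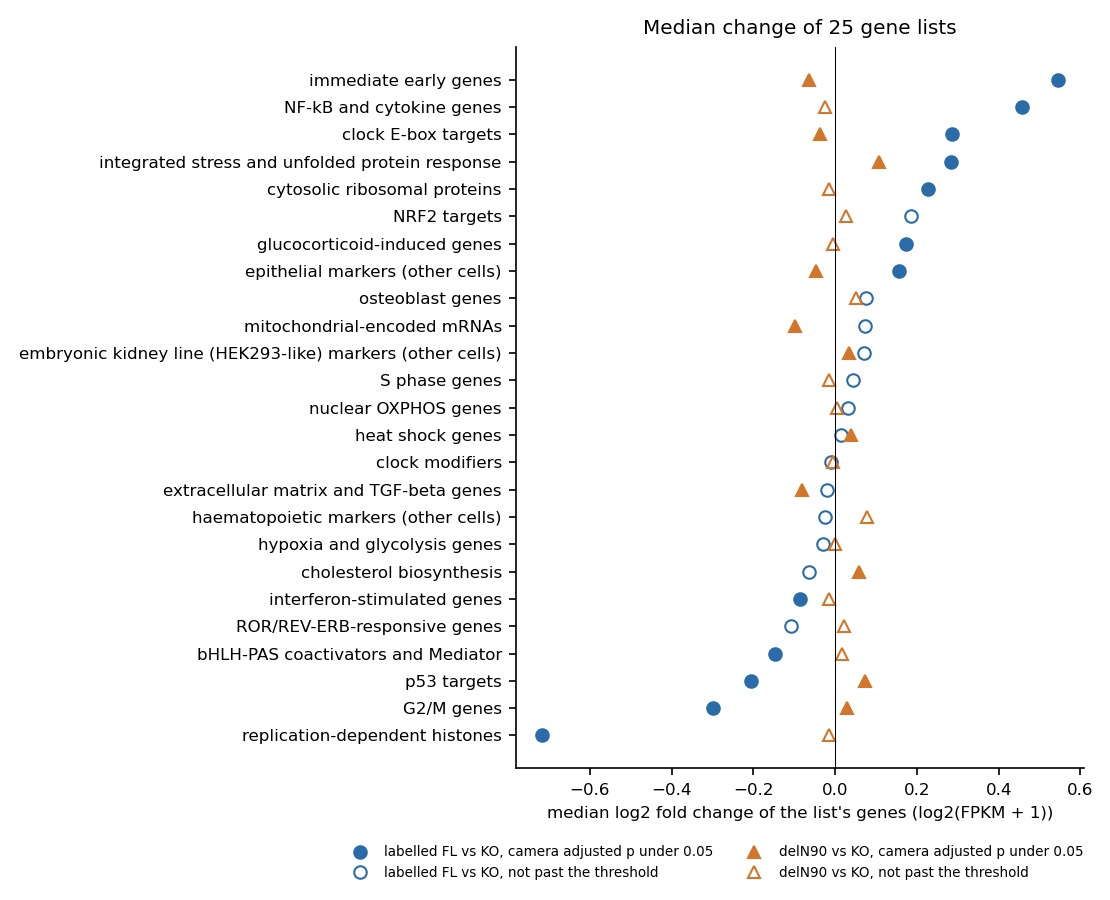
Median log2 fold change on the log2(FPKM + 1) scale of the measured members of each of 25 gene lists, for the libraries labelled FL against KO (circles) and delN90 against KO (triangles), filled where camera with the preset correlation had an adjusted p under 0.05. Medians ran from −0.72 (histones) to 0.55 (immediate early genes) for the libraries labelled FL and from −0.10 (mitochondrial-encoded mRNAs) to 0.11 (stress and unfolded protein response) for delN90.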

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

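The window spread, the BMAL1 ratio, the E-box percentile and the fate of the changes of at least 1 in log2 were chosen as tests after the results were seen, and the predictions of the other tests were written before they were run. Among effects against KO that differed between delN90 and the libraries labelled FL, by the test of these groups against each other, were BMAL1 (log2 difference 5.22), DDIT3 (0.523) and the clock E-box list (median −0.293). The list's call was lost at adjusted p = 0.126 with an estimated correlation, and 8886 single genes differed between these groups.

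BMAL1 transcript in the libraries labelled FL was 0.82 of the KO level, while the median of E-box targets lay at percentile 100 of 10000 random lists matched on expression (95% of these between −0.14 and 0.09). Neither value separates the explanations. Control cells described under another name, as the Ctrl descriptions would have it, would give active endogenous BMAL1 without a transgene. A full-length transgene with altered codons would give active protein whose transcript is not counted at the gene. The delN90 transcript was counted there (20282 to 24160 reads), so such a transgene would have to differ from delN90 in its codons. Reads across the transgene junction or the edited site would decide, and the deposited table does not hold them. Until then, differences of the libraries labelled FL from KO and from delN90 may be those of control cells from a knockout clone.

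The 8754 genes that differed between the libraries labelled FL and KO were weighed against depth, GC content or gene length, and chromosome blocks. Removing the GC and length trend left 97.9% of the count, thinning to equal depth left 96.8%, and subtracting the median of 50 neighbouring genes left 84.9%, although only 69.7% of the original genes were still called in the same direction. Neighbouring genes did differ together, since 0 of 1000 random gene orders had an SD of window medians as large as the observed 0.128 (mean of random orders 0.0383). The strongest windows were on chromosome 1 from 14404 to 1662602 (median −0.77) and chromosome 8 from 22613908 to 30766470 (−0.56). Copy number differences between cell populations of 1 line would give such windows. For delN90 against KO the SD was only 0.0123 (mean of random orders 0.0108, 2 of 1000 as large). For delN90 against the libraries labelled FL it was 0.132 (0.039). The libraries labelled FL thus stood apart in these windows from both other groups. Control cells or a separate clone with a transgene would each give this. Of the changes of at least 1 in log2, 98.8% stayed called in the same direction. That share cannot exclude copy number for the large changes. No window median reached 1 in size, and a median of 50 genes does not remove a gain or loss of a few genes. Copy number thus can account for part of the small changes, and its part in the large ones stays open. A biological effect of BMAL1 cannot be told from a difference between clones here.

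The ER chaperone genes that were higher in delN90 than in KO were weighed against a single library, depth, and GC content or gene length. At least 5 members of the stress list were called higher whichever of the 6 libraries was left out, against 9 with all of them. Thinning left 8 and removing the GC and length trend left 8, with HSPA5 at log2 fold changes of 0.552 and 0.551, so these technical explanations do not account for the rise. Strong expression of a truncated protein, at 42.3-fold the KO transcript, or a function of BMAL1 kept by delN90 could, and no control with another overexpressed protein was present to separate them. HSPA5 (208.2 FPKM), HYOU1 (48.46) and CALR (1120) were higher still in the libraries labelled FL, where BMAL1 transcript was 0.82 of KO, so high BMAL1 transcript was not needed for high levels of these genes, although the cause may differ between the groups.

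Regrouping the 6 libraries of each comparison gave 10 splits, too few for a share under 0.05. The real split had the highest count in 1 of 10 each time, with 8754, 20 and 8886 genes, and the highest other counts were 0, 1 and 0.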

How the results depend on the processing

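Pseudocounts of 0.1 and 0.01, the prior without the robust step, GC and length removal, thinning and neighbourhood subtraction were chosen after the results were seen. Each leading result was compared under each alternative. Of these comparisons, 172 stayed, meaning a count within 1.5 times or a list call kept in its direction. In the others, 15 counts moved by over 1.5 times, 9 calls were lost and none reversed. The size of list medians was not part of this rule. Among single genes, 7954 values stayed, 56 were lost, 30 gained and 4 changed sign without passing. Genes changed between the libraries labelled FL and KO ranged from 7309 to 9152, apart from a limit of 1 on the size of log2 fold changes, which left 253, 1 and 264 genes in FL against KO, delN90 against KO and delN90 against FL by its construction. For delN90 against KO, limma-voom gave 90 genes (59 shared with FL against KO), protein-coding genes alone 33, neighbourhood subtraction 31, and the 2 groups alone 10, with 5 stress list members. Leaving out 1 library gave 12 to 32 genes (12 without KO replicate 1, 13 without KO replicate 2, 32 without delN90 replicate 1), 10 to 24 shared with FL against KO (10 without KO replicate 1 and 10 without KO replicate 2), and 5 to 9 stress list members (5 without delN90 replicate 2). The E-box median in delN90 against KO ran from −0.0391 to −0.0131 when 1 library was left out, and was −0.0183 after thinning (adjusted p = 0.0968), −0.0367 with an estimated correlation (adjusted p = 0.33) and −0.0367 by fry (adjusted p = 0.161). With an estimated correlation the E-box medians of 0.285 in FL against KO and −0.293 in delN90 against FL lost the call (adjusted p = 0.151 and 0.126). Neighbourhood subtraction changed the sign of ZBTB16 (−0.0702 in FL against KO, 0.07 in delN90 against FL) and TYMS (−0.0186 and 0.0158). None of these values passed (limma adjusted p = 0.0534 and 0.0533 for ZBTB16, 0.61 and 0.666 for TYMS). ZBTB16 was near 0, at 0.0253 FPKM in KO and 0.136 in FL. The cause of these changes was not tested. A replicate block gave 8480, 19 and 8620 genes. The fit without a block was fixed before the data were examined, and residuals of same-number replicates did not correlate (r −0.046 to 0.062 over 9 pairs). Scaling by library size only and no filter equal the reported setting. Neither the edgeR test planned for counts nor the count-based alternative with DESeq2 was run, although whole reads were recovered and limma-voom was fitted to them. A minimum mean of 1 CPM removed 455 genes. Thinning to the smallest library gave 8474, 24 and 8615 genes, and what a greater depth would add was not tested. With 3 libraries per group at these depths, 22% of simulated 1.2-fold changes of well-expressed genes were called between delN90 and KO.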

Other observations

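The terms and small RNAs described here were picked after the results were seen. Annotation terms for structural genes were enriched between the libraries labelled FL and KO, whose BMAL1 transcript goes against the label. Among the genes with a log2 fold change of at least 1 on the log2(FPKM + 1) scale, 6 of 28 annotated to the term collagen trimer were present where 0.216 were expected (hypergeometric adjusted p = 9.39e-05), namely COL3A1, COL5A2, COL5A3, COL8A1, EMILIN1 and MARCO. COL3A1 and COL5A2 also belong to the fixed extracellular matrix and TGF-beta list, which did not pass camera (adjusted p = 0.728, 8 higher and 8 lower), and COL4A1, COL4A2, COL6A1 and COL6A2 of that list were lower. Among those with a log2 fold change of −1 or below, 7 of 31 keratin filament entries were present (hypergeometric adjusted p = 3.21e-07). They were KRT75, KRT81, KRT86, repeated entries of KRT87P, ENSG00000287051 and ENSG00000257500, all on chromosome 12. Their reads may be shared between near-identical copies. The test counts these entries as independent genes, so its p-value overstates the enrichment. The abundant members KRT8 (107.9 ± 1.37 to 161.4 ± 2.02 FPKM from KO to FL, limma adjusted p = 4.75e-07) and KRT18 (55.08 ± 0.476 to 81.08 ± 3.36 FPKM, adjusted p = 2.44e-06) were higher. Of 92 homophilic cell adhesion genes, 42 were higher where 20.2 were expected (adjusted p = 1.93e-04), and others were lower, such as FAT1 (23.16 ± 0.11 to 15.62 ± 0.465 FPKM from KO to FL), DCHS2, DSG2, CDH2 and CDH4, although the clustered protocadherins in the term share exons and so may share reads.

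Small RNAs varied between single libraries of delN90. SNORD3C stood at 47.73 FPKM in delN90 replicate 1 and at 5.441 to 8.544 FPKM in the other 8 libraries, and RN7SL3 at 14.76 FPKM against 5.107 to 7.432. RNU2-2P stood at 10.81, 1.13 and 0.4446 FPKM in delN90 replicates 1, 2 and 3.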
